A study of Streptomyces chattanoogensis with 18 samples.

How the data were processed

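Total RNA from mycelium was labelled with Cy3 and hybridised to a custom one-colour Agilent array, per the labels' protocols. The deposited scanner files, 1 per array, were written by Feature Extraction 10.7.3.1, per the file headers. The values used from them are processed intensities, from which the scanner software had subtracted the background and removed the spatial trend, per the file headers, with no scaling between arrays. Raw median intensities of spot and local background and the spot flags came from the same deposited files. The deposited series matrix holds 1 value per probe and array on a log2 scale. Set against the scanner values, each of its columns correlated at 0.998 or more, and its columns shared identical sorted values within the 6 arrays of 16 h and within the 12 arrays of 12 and 24 h, so the authors had quantile-normalized the sets separately. The column medians were 6.35 for 16 h and 5.27 for the other times. The series matrix holds absolute log2 levels in the direction of the scanner values, and its background treatment is not given in the sources used here. It was used as an alternative for comparisons within a set.

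Groups were taken from the labels as strain and time, with 3 arrays each. The file headers put the arrays on 3 slides scanned on 2 days. Slide 1, scanned on the first day, held all 16 h arrays of both strains. Slide 2 held the wild-type and slide 3 the mutant arrays of 12 and 24 h. Each group lies on 1 slide, so slide adds nothing as a block to a fit with the groups, and comparisons within a slide were also fitted alone.

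The array holds 8173 non-control probes. Of these, 7401 carry an ORF number up to L10.orf8117, 700 carry a custom ID only, and 72 are named for contig ends. The design text counts 8117 protein-coding genes. No ORF number had more than 1 probe, so probes of a gene did not need to be combined. Since no gene names were paired with IDs, the probe was the unit of each test. The gene lists fixed in advance and the check of scgA were not run.

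Control spots and spots with an outlier flag were left out, 108 to 294 flagged spots per array, and no spot was saturated. The log2 processed signal of each array was set relative to the 75th percentile of its non-control probes, after spots of a probe had been averaged. Probes well above background on all arrays of at least 1 group were tested, 7650 in number: 6944 with an ORF number, 642 with a custom ID and 64 for contig ends. limma 3.58.1 in R 4.3.3 fitted all 18 arrays with 1 mean per group, and contrasts were tested with its moderated two-sided test. Probes with a Benjamini-Hochberg adjusted p under 0.05 were called, and the number changed at least 2-fold is given beside each count. A probe well above background on none of the arrays of a group has only a bound there, and where only some arrays of a group measured it, the fitted value is given with their number. The fold of a bound is given as at least the bright group's mean over the dim group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Medians of stretches are of fitted log2 values, and the median with such groups at their bound is given beside those it changed. The precision rests on 3 arrays per group, and the median standard error of a log2 difference was 0.24, or 0.34 for a difference between the strains' changes.

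Runs are at least 5 neighbouring tested probes called in 1 direction. Neighbours follow the probe numbers of the array design, over 7586 tested probes, leaving out the contig ends. The ORF numbers rise with the probe numbers with 0 exceptions. The number of runs was compared with 1000 shuffles of the order, also under the alternatives, a step added after the data were examined. With no gene names, the rule for naming probes fixed before the data were examined allows at most 2 IDs that rose and 2 that fell per main comparison, the largest fitted changes among called probes whose 2 groups do not overlap (for the difference between the strains' changes, among called probes). It adds the first and last probe of the longest run in each direction. The main comparisons were the strains at each time, 24 against 12 h in each strain, and the difference between these. With 3 arrays against 3, chance alone separates 10% of probes completely.

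The procedure was tested on simulated data for the 16 h comparison with 7650 probes, 200 of them changed. It recovered 56% of the probes changed 2-fold and 92% of those changed 4-fold, with 4 false among 152 calls. The simulated noise was independent between probes, and far fewer probes changed than were called in the real data. These rates therefore need not hold for the real comparisons.

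The alternatives were scaling on the median, quantile normalization, the series matrix, no filter on dim probes, only probes well above background on all 18 arrays, limma's trend and robust options, only the arrays of the groups compared, the replicate letter as a block, each array left out in turn, and runs of at least 4. Normexp correction with an offset of 50 was planned on mean signals and run on median signals instead. Scaling on 8 Agilent spike-in probes was added. Both were chosen after the data were examined.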

Results

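Streptomyces chattanoogensis L10 is a filamentous bacterium known as a producer of the antifungal natamycin, and scgA is known as an AfsA-type gene of gamma-butyrolactone signal synthesis. Transcript levels were measured in mycelium of the wild type L10 and of ZJUD7, a deletion mutant of scgA called the mutant here. Both strains were grown in the liquid medium YEME and collected at 12, 16 and 24 h, a stage that the labels call exponential at each time. One-colour arrays gave 3 values per strain and time, 18 arrays in 6 groups. Of 8173 probes, 6493 to 7809 were well above background on an array. The median processed signal of an array lay between 26.1 and 97.2, and the 24 h arrays were the dimmest, at 26.1 to 27.6 in the mutant and 35.7 to 41.1 in the wild type. Within a group, arrays correlated across probes at 0.926 to 0.985, and the median SD of a probe was between 0.17 and 0.30 on the log2 scale. The labels do not say whether the 3 arrays of a group came from separate cultures, so p-values measure the spread between these arrays, which can be partly technical. The files pair no probe ID with a gene name, so probes are given by ID, and the level of scgA itself and lists of genes by function were not analysed here.

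The first question was how the deletion changed transcript levels at each time. At 12 h, L10.orf6986 and L10.orf2471 were lower in the mutant. L10.orf6986 stood at 5.28 ± 0.39 (SD, n = 3, log2 relative to the 75th percentile of the array) in the wild type and was not well above background in the mutant, at least 732.5-fold lower (adjusted p = 7.77e-13). The loss was not seen at 16 h, where L10.orf6986 stood at 4.64 ± 0.46 in the mutant and 4.93 ± 0.22 in the wild type (SD, n = 3). That difference was not called (adjusted p = 0.387), and the one at 24 h was -1.209 (adjusted p = 0.00119). L10.orf2471 was at least 254-fold lower (adjusted p = 2.04e-08), from 3.75 ± 0.36 (SD, n = 3) in the wild type. Among raised probes, L10.orf0136 was not well above background in any wild-type array and reached 1.71 ± 0.09 (SD, n = 3) in the mutant, at least 68.7-fold higher (adjusted p = 1.04e-10). CUST_153_PI427711755 was at least 54.3-fold higher (adjusted p = 1.45e-09). The longest stretch of neighbouring raised probes ran from CUST_7248_PI427711755 to CUST_7278_PI427711755, where all 31 tested probes were higher in the mutant, with a median log2 difference of 2.40. The longest lowered stretch ran from L10.orf5490 to L10.orf5505, where all 16 tested probes were lower in the mutant, with a median of -2.93. In 8 of them the mutant was not well above background, and with these at their bound the median was -2.59.

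In all, limma called 3335 of 7650 probes different between the strains at 12 h, 1582 higher and 1753 lower in the mutant, and 1920 of them changed at least 2-fold. The median of all probes lay at -0.14, and the share of higher calls was 47.4%, against 55.4% with median scaling, 57.4% with quantile normalization, 57.45% in the authors' series matrix and 44.8% with spike-in scaling. The mutant arrays of this time lay on 1 slide and the wild-type arrays on another. Between these same 2 slides, the differences of 12 and 24 h correlated at 0.292 across probes, where their errors allow 0.929. That argues against the slide as the whole cause, but a part from the slide cannot be told apart from the strain here. A fit to the arrays of 12 h alone called 3817 probes. Normexp background correction, with an offset that shrinks the differences of dim probes, gave 558 calls, a median of -0.59 for the stretch from L10.orf5490, and log2 differences of -5.95 for L10.orf6986, -4.33 for L10.orf2471, 2.74 for L10.orf0136 and 2.25 for CUST_153_PI427711755.

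At 16 h, L10.orf2471 and its neighbour L10.orf2472 were lower in the mutant. L10.orf2471 went from 5.67 ± 0.48 (SD, n = 3) in the wild type to -3.99 ± 0.53 (SD, n = 3), a log2 difference of -9.66 ± 0.56 (SE, adjusted p = 6.48e-09). L10.orf2472 differed by -9.16 ± 0.42 (SE, adjusted p = 7.11e-10), and both were well above background on only 2 of the 3 mutant arrays. L10.orf0136 was again not well above background in the wild type and was at least 16.1-fold higher in the mutant (adjusted p = 2.08e-09). L10.orf6626 was higher by 5.17 ± 0.43 (SE, adjusted p = 2.28e-07), at 3.36 ± 0.07 (SD, n = 3) against -1.81 ± 0.88 (SD, n = 3). At the other times L10.orf6626 was lower in the mutant, with differences of -2.167 at 12 h (adjusted p = 0.000779) and -3.385 at 24 h (adjusted p = 1.81e-05). The longest raised stretch ran from L10.orf3097 to L10.orf3118, where 22 of 22 probes were higher in the mutant, with a median log2 difference of 1.31. At 12 h, 9 probes of this stretch had been lower in the mutant and 1 higher. The longest lowered stretch was again L10.orf5490 to L10.orf5505, where 16 of 16 probes were lower in the mutant, with a median of -1.83.

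At this time 3103 probes were called, 1458 higher and 1645 lower, and 1819 changed at least 2-fold. All 6 arrays shared 1 slide, and a fit to these arrays alone called 2889. The share of higher calls was 47.0%, against 56.2% with median scaling, 54.0% with quantile normalization, 54.1% in the authors' series matrix and 35.3% with spike-in scaling. Normexp background correction gave 1052 calls, medians of -0.61 for the stretch from L10.orf5490 and 0.73 for that from L10.orf3097, and log2 differences of -6.90 for L10.orf2471, -6.27 for L10.orf2472, 2.06 for L10.orf0136 and 3.58 for L10.orf6626.

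At 24 h, L10.orf1810 and L10.orf1812 were lower in the mutant. L10.orf1810 stood at 3.31 ± 0.86 (SD, n = 3) in the wild type and was not well above background in the mutant, at least 97.2-fold lower (adjusted p = 7.15e-09). L10.orf1812 was at least 72.9-fold lower (adjusted p = 1.31e-09). L10.orf0136 was at least 18.7-fold higher in the mutant (adjusted p = 9.54e-10). CUST_141_PI427711755, which stood at -2.05 ± 0.12 (SD, n = 3) in the mutant at 12 h, reached 3.79 ± 0.19 (SD, n = 3) at 24 h, higher than in the wild type by 6.41 ± 0.22 (SE, adjusted p = 5.9e-11). All 25 tested probes from CUST_7249_PI427711755 to CUST_7273_PI427711755 were higher in the mutant than in the wild type, with a median log2 difference of 2.13. This median was 1.58 without wild-type replicate A and 2.89 without wild-type replicate C. All 23 probes from L10.orf5143 to L10.orf5165 were lower in the mutant than in the wild type, with a median of -1.89. The same 23 probes gave 20 lower calls at 16 h, and 2 higher and no lower calls at 12 h.

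The 24 h comparison called 3040 probes, 1584 higher and 1456 lower, with 1736 changed at least 2-fold. The 2 strains again lay on different slides. The 24 h differences correlated at 0.292 across probes with those of the earliest time, where their errors allow 0.929. Both were measured between the same 2 slides, so this argues against the slide as the whole cause. A part from the slide cannot be told apart from the strain here. A fit to the 6 arrays of 24 h alone called 2024 probes, where such fits called 3817 at 12 h and 2889 at 16 h. The similar counts of the 3 times thus depended on the spread shared in 1 fit. The median SD of a probe at 24 h was 0.25 in the mutant and 0.30 in the wild type, against 0.17 and 0.20 at 12 h. Normexp background correction called 510, with log2 differences of -3.83 for L10.orf1810, -3.42 for L10.orf1812, 1.87 for L10.orf0136 and 4.11 for CUST_141_PI427711755. The median of all probes lay at 0.18, and at -0.28 with spike-in scaling. The share of higher calls was 52.1%, against 49.6% with median scaling, 49.5% with quantile normalization, 49.1% in the authors' series matrix and 17.4% with spike-in scaling.

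**Figure D1:**
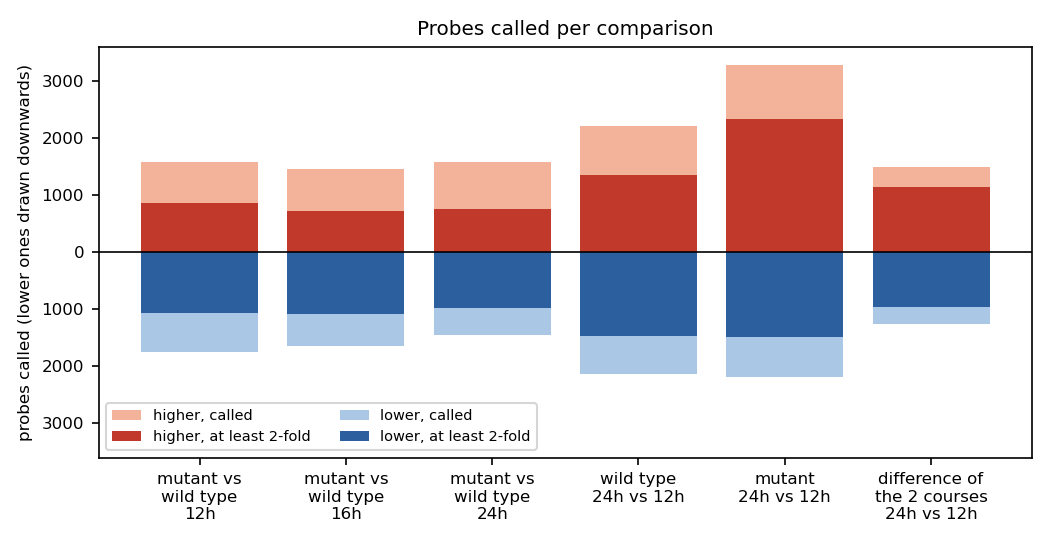
Probes called by limma in 6 comparisons, with higher ones drawn upwards and lower ones downwards from 0, and the part changed at least 2-fold in the darker colour. The mutant's change from 12 to 24 h has the most calls, 5467 of 7650 probes.

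Across the 3 times, 225 probes were higher in the mutant at every time and 324 were lower at every time, where independent lists would share 62.4 and 71.7. At 1 time or more, 5553 probes were called, and 1058 of these were called in opposite directions at different times. Probes higher at both 12 and 24 h numbered 622, against 327.6 for independent lists, and probes lower at both numbered 623, against 333.6. The corresponding numbers for 12 and 16 h were 501 against 301.5 and 616 against 377, and those for 16 and 24 h were 419 against 301.9 and 635 against 313.1. No arrays were shared between these comparisons, but those of 12 and 24 h set the same 2 slides against each other. All 3 took each probe's spread from 1 fit, so probes with little spread are called together more often than independent lists allow. Calls higher then lower and lower then higher numbered 324 and 277 for 12 and 16 h, against 340.2 and 334.1. They numbered 207 and 155 for 12 and 24 h, against 301.1 and 363, and 191 and 290 for 16 and 24 h, against 277.5 and 340.6. With spike-in scaling, 43 probes were higher at every time, and with normexp background correction 7 were higher and 48 lower.

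**Figure D2:**
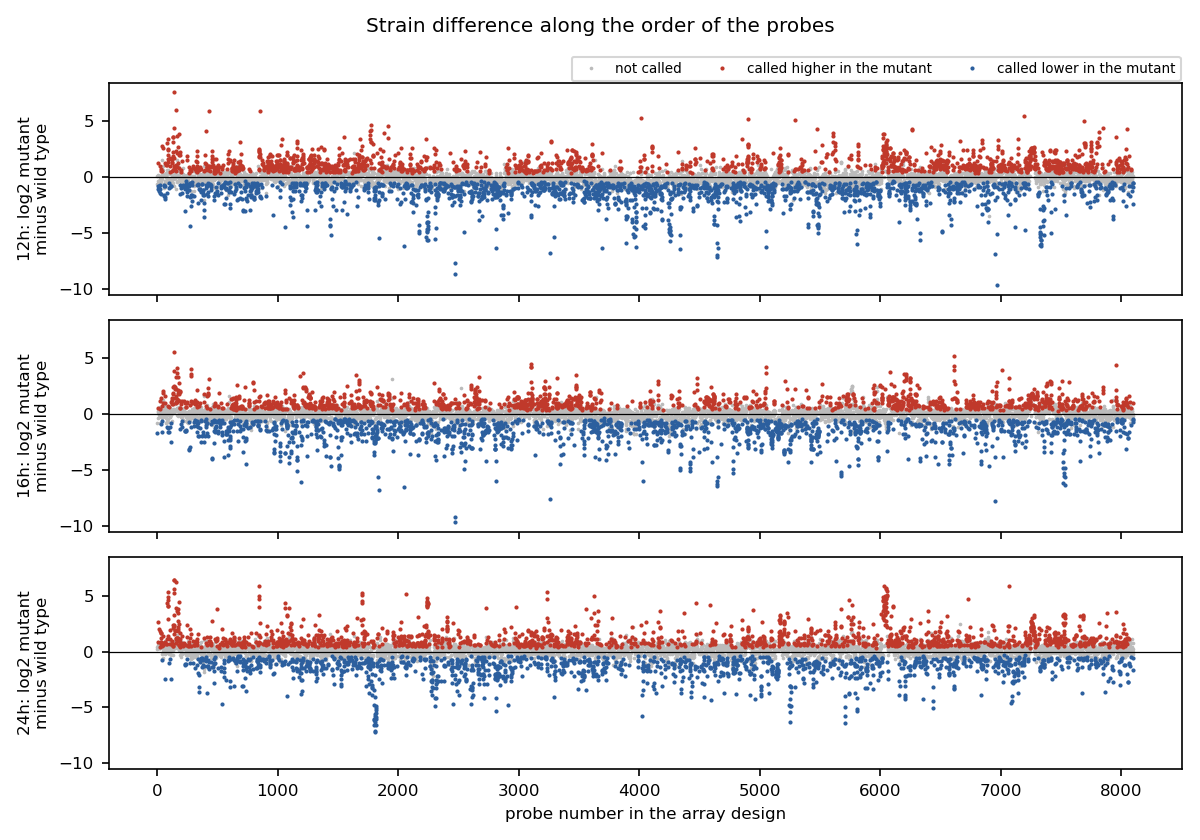
Log2 difference between mutant and wild type (vertical axis, 1 panel per time) for each tested probe, against its number in the array design (horizontal axis), with called probes in colour. Called probes of 1 direction stand in groups of neighbours, such as the 16 lowered probes from L10.orf5490 to L10.orf5505 at 12 and 16 h.

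Called probes lay next to each other more often than in shuffled order. At 12 h there were 108 runs of at least 5 neighbouring probes called in 1 direction, 47 higher and 61 lower, and none of 1000 shuffles of the order gave more than 16. At 16 h there were 101 runs, 48 higher and 53 lower, against at most 11 in shuffles. At 24 h there were 82, 36 higher and 46 lower, against at most 12, and a fit to the 24 h arrays alone gave 46, against at most 4. With normexp background correction the runs fell to 10 at 12 h, 18 at 16 h and 12 at 24 h, where shuffles of its calls gave at most 0, 1 and 1. Order was taken from the probe numbers of the array design, which follow the ORF numbers without exception, and genome coordinates were not used here.

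The second question was how each strain changed over time. In the wild type, L10.orf6990 rose from 12 to 24 h by 8.55 ± 0.28 (log2, SE, adjusted p = 1e-11) and L10.orf5164 by 8.49 ± 0.37 (SE, adjusted p = 9.69e-11). L10.orf5164 lies in the longest raised stretch, L10.orf5141 to L10.orf5166, where 26 of 26 probes rose with a median of 7.34. L10.orf2177 changed by -8.26 ± 0.52 (SE, adjusted p = 3.86e-09) and L10.orf3105 by -7.22 ± 0.50 (SE, adjusted p = 9.07e-09). L10.orf2177 was well above background on 1 of the 3 wild-type 24 h arrays, and its change was -9.01 without the 24 h replicate A and -7.70 without the 24 h replicate C. The longest lowered stretch ran from L10.orf7260 to CUST_7273_PI427711755, where 29 of 29 probes fell with a median of -2.02. This median was -1.45 without the 24 h replicate A and -2.77 without the 24 h replicate C. Over the other alternatives it lay between -2.86 and -1.63.

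In the mutant, L10.orf2247 rose by at least 449-fold from 12 to 24 h (adjusted p = 1.68e-09) and L10.orf2244 by at least 579-fold (adjusted p = 3.35e-09). Neither was well above background in the mutant at 12 h, and they reached 4.58 ± 0.18 and 4.94 ± 0.08 (SD, n = 3). L10.orf0432 changed by -7.44 ± 0.26 (SE, adjusted p = 4.54e-11). L10.orf3477 fell at least 21.2-fold (adjusted p = 7.23e-11), to a signal not well above background at 24 h. The stretch from L10.orf5141 to L10.orf5166 was the longest raised one in the mutant too, with 26 of 26 probes higher and a median of 4.76. The longest lowered stretch, L10.orf7251 to L10.orf7289, held 39 probes with a median of -2.12.

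From 12 to 24 h, 4346 probes were called in the wild type, 2213 higher and 2133 lower, and 5467 in the mutant, 3289 higher and 2178 lower. Of these, 2809 and 3828 changed at least 2-fold. Each strain's 12 and 24 h arrays shared 1 slide, and fits to these arrays alone called 4044 and 5472. Probes higher at 24 h in both strains numbered 1588, against 951.4 for independent lists, and probes lower in both numbered 1490, against 607.3. Opposite directions were called for 162 and 152 probes. Runs of at least 5 neighbours numbered 150 in the wild type, with at most 34 in shuffles. In the mutant they numbered 222, of which 153 were higher and 69 lower, where shuffles gave 63.6 higher and 10.1 lower on average. With normexp background correction there were 24 in the wild type and 22 in the mutant, against at most 2 in shuffles, and with spike-in scaling 259 and 282, against at most 156 and 202.

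The split of these calls depended on the scaling. In the mutant the median of all probes lay at 0.37, and 60.2% of the calls were higher at 24 h, against 50.7% with median scaling, 48.7% with quantile normalization, 48.5% in the authors' series matrix and 10.9% with spike-in scaling. In the wild type the share was 50.9%, against 45.1% with median scaling, 47.0% with quantile normalization, 46.8% in the authors' series matrix and 17.4% with spike-in scaling. Spike-in scaling put the median of all probes at -0.73 in the wild type and at -0.88 in the mutant, and the median of L10.orf7251 to L10.orf7289 in the mutant at -3.37. Normexp background correction called 1384 probes in the wild type and 1354 in the mutant. With it L10.orf2247 rose by 4.95 and L10.orf2244 by 5.50 in the mutant, L10.orf0432 changed by -5.04 and L10.orf3477 by -2.06, and the medians of L10.orf5141 to L10.orf5166 were 5.36 in the wild type and 3.11 in the mutant. In the wild type it put L10.orf6990 at 6.05, L10.orf5164 at 6.87, L10.orf2177 at -5.01 and L10.orf3105 at -5.13. Spike-in scaling put L10.orf0432 at -8.70 in the mutant, and L10.orf2177 at -9.09 and L10.orf3105 at -8.05 in the wild type.

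Comparisons with 16 h within a strain set arrays of different slides and scan days against each other, and slide and time cannot be told apart there. The wild type had 2714 calls from 12 to 16 h, 1225 higher and 1489 lower, and 3795 from 16 to 24 h, 1996 higher and 1799 lower. The mutant had 3608 calls from 12 to 16 h, 1796 higher and 1812 lower, and 4510 from 16 to 24 h, 2726 higher and 1784 lower. From 16 to 24 h the share of higher calls was 52.6% in the wild type, against 49.9% with median scaling, 47.8% with quantile normalization and 13.1% with spike-in scaling. In the mutant it was 60.4%, against 49.7% with median scaling, 48.4% with quantile normalization and 10.2% with spike-in scaling. Spike-in scaling put the median of all probes at -0.83 in the wild type and at -0.91 in the mutant for this interval. With normexp background correction the 4 counts were 821, 1171, 504 and 909. With the replicate letter as a block and only the arrays compared, they were 2909, 2733, 716 and 1742. In the stretch from L10.orf5143 to L10.orf5165, 23 of 23 probes rose from 12 to 16 h in the wild type, with a median of 11.2-fold, and 21 of 23 in the mutant, with a median over the 23 of 2.82-fold.

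The third question was whether the strains changed differently over time. From 12 to 24 h, L10.orf2247 rose more in the mutant than in the wild type by at least 8.32 on the log2 scale, with a fitted value of 9.81 ± 0.74 (SE, adjusted p = 3.49e-07). In the wild type it stood at -0.13 ± 1.23 at 12 h and at 0.36 ± 0.77 at 24 h (SD, n = 3). L10.orf2244 differed by at least 8.68, with a fitted value of 9.67 ± 0.80 (SE, adjusted p = 7.73e-07). Neither was well above background in the mutant at 12 h, so the bounds are what was measured. Without wild-type 12 h replicate A the fitted value of L10.orf2247 was 10.46, and without wild-type 12 h replicate B that of L10.orf2244 was 9.04. Both lie in the stretch from L10.orf2234 to L10.orf2252, where all 19 probes had a higher change in the mutant, with a median of 5.92. In this stretch 17 probes were lower and 1 higher in the mutant at 12 h, with a median of -4.07, or -4.04 with groups not well above background at their bound, and 16 were higher and none lower at 24 h, with a median of 4.01. L10.orf7207 differed by -7.76 ± 0.40 (SE, adjusted p = 1.01e-08). It went from 1.70 ± 0.10 to -1.63 ± 0.20 in the mutant and from -3.75 ± 0.39 to 0.68 ± 0.59 in the wild type (SD, n = 3). L10.orf1774 differed by -7.29 ± 0.60 (SE, adjusted p = 7.6e-07) and was well above background on 1 of the 3 mutant arrays of 24 h. All 23 probes from L10.orf5143 to L10.orf5165 rose less in the mutant, with a median difference of -2.42.

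**Figure D3:**
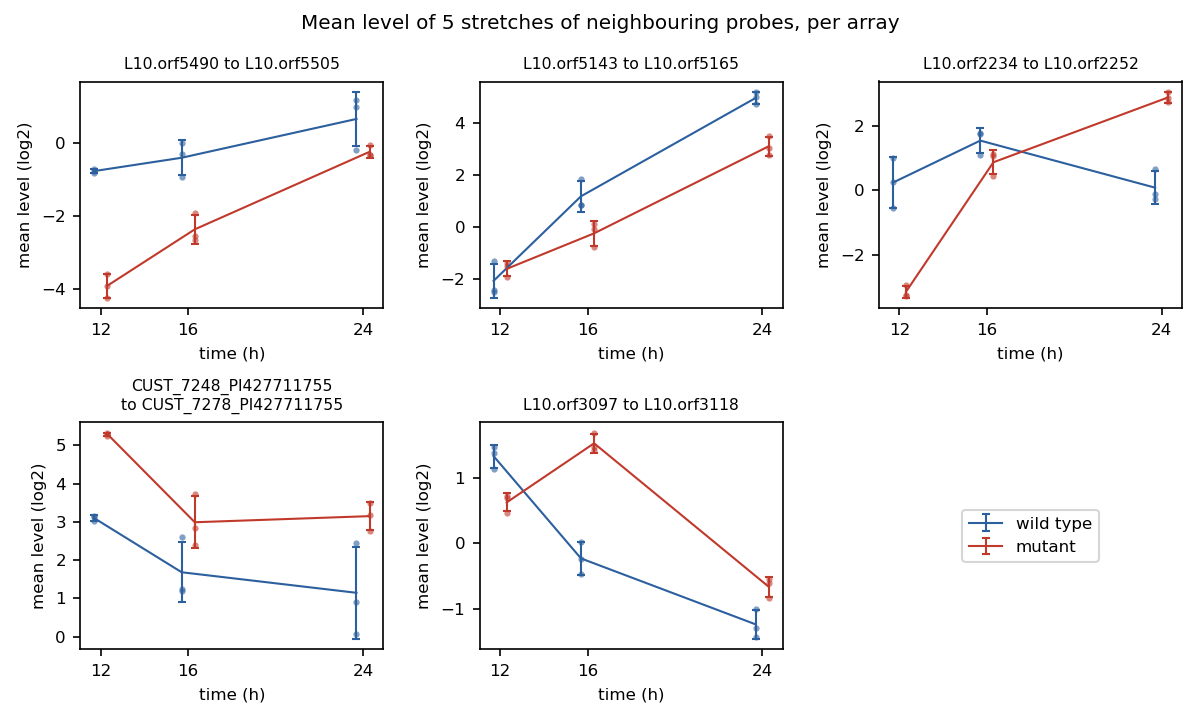
Mean level of the tested probes of 5 stretches (vertical axis, log2 relative to the 75th percentile of the array) at 12, 16 and 24 h (horizontal axis, points shifted sideways by strain), with dots for arrays and lines joining group means with SD bars (n = 3). In L10.orf2234 to L10.orf2252 the mutant goes from -3.16 to 2.90, while the wild type is at 0.24 at 12 h and at 0.08 at 24 h.

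The change from 12 to 24 h differed between the strains for 2745 probes, 1496 with a higher and 1249 with a lower change in the mutant, and 2107 of them by at least 2-fold. This difference removes a slide effect that adds the same log2 value at both times, since each strain's 12 and 24 h arrays shared a slide. The median of all probes lay at 0.22, and the share of calls with a higher change was 54.5%, against 44.5% with median scaling, 44.0% with quantile normalization, 43.8% in the authors' series matrix and 27.4% with spike-in scaling, where the median lay at -0.20. Normexp background correction called 296, with values of 4.65 for L10.orf2247, 5.12 for L10.orf2244, -3.55 for L10.orf7207 and -2.53 for L10.orf1774, and a median of 2.97 for the stretch from L10.orf2234. Runs of at least 5 neighbours numbered 68, 37 higher and 31 lower, against at most 10 in shuffles. They numbered 43 among probes well above background on all 18 arrays, against at most 10, and 5 with normexp background correction, against 0.

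From 12 to 16 h the change differed for 2760 probes, 1324 higher and 1436 lower, and from 16 to 24 h for 2662, 1404 higher and 1258 lower. Both set the 16 h difference, measured within 1 slide, against a difference between 2 slides. Normexp background correction called 523 and 532. For the change from 16 to 24 h, the share of higher calls was 52.7%, against 43.2% with median scaling, 43.6% with quantile normalization and 34.4% with spike-in scaling.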

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

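The counts over other splits of the arrays were fixed before their results were seen, and the other tests in this part were chosen after. The strains' changes over time differed, by a test of the difference itself, for 2745 probes from 12 to 24 h, 2760 from 12 to 16 h and 2662 from 16 to 24 h. The 4 named probes were L10.orf2247 at 8.32 or more (fitted 9.81), L10.orf2244 at 8.68 or more (fitted 9.67), both with a mutant 12 h group not well above background, L10.orf7207 at -7.76 and L10.orf1774 at -7.29 on the log2 scale from 12 to 24 h. Of the 200 splits of the strain labels within each time, 100 were run. Among these, only the real split gave as many calls from 12 to 24 h (1 of 100, highest other 1713) and from 12 to 16 h (1 of 100, highest other 2011). From 16 to 24 h, 2 of 100 splits gave as many. The other one, with 3594 calls, exchanged all 6 arrays of 16 h between the strains, which tests the sum of the 16 and 24 h differences and so points to a structure of the samples, and the next highest gave 1465. The same exchange was not among the splits run for the other intervals, and as a separate test it gave 3648 calls from 12 to 24 h and 3529 from 12 to 16 h, more than the real splits. Shuffling within each time also breaks up the strain difference itself, so these splits test for no strain difference at any time. They cannot decide whether chance accounts for a difference between the strains' changes, and the arrays shuffled may not be separate cultures.

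For the comparisons of 3 arrays with 3, the 10 splits are too few for a share under 0.05, and in each only the real split, 1 of 10, gave as many calls. Every other split mixes the groups compared, so a difference between them raises the spread within the mixed groups and lowers the calls. The low counts of the other splits are therefore not separate evidence. Between strains the real and the highest other counts were 3335 and 0 at 12 h, 3103 and 118 at 16 h, and 3040 and 156 at 24 h. In the wild type they were 4346 and 0 from 12 to 24 h, 2714 and 10 from 12 to 16 h, and 3795 and 3 from 16 to 24 h. In the mutant they were 5467 and 0, 3608 and 1, and 4510 and 70.

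The strain differences at 12 and 24 h were measured between the same 2 slides. A slide effect as the whole cause would add the same log2 difference at both times, so that the differences would correlate across probes near the 0.929 that their errors allow. The correlation was 0.292 (probes are not independent replicates), which argues against the slide as the whole cause. The covariance exceeded the higher one of a pair with 16 h, which lies within 1 slide, by 0.0614, at 0.408 against 0.347. A slide effect may account for part of the differences and cannot be told apart from the strain there.

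At 16 h, between the lower level in the mutant at 12 h and the higher level at 24 h, L10.orf2247 stood at 1.01 ± 0.50 in the mutant and 1.92 ± 0.61 in the wild type (SD, n = 3).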

How the results depend on the processing

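Normexp on median signals and spike-in scaling were chosen after the data were seen, and all other alternatives before. The 24 named probe values kept their direction and stayed called in all 222 values under the alternatives, with adjusted p up to 0.0233, and in all 168 values with 1 array left out. Most of the 24 had no value when only probes well above background on all 18 arrays were tested. The named probes had been picked as the largest called changes in these same data, so their staying called is weak evidence. With 1 array left out, no count of calls or runs of a comparison moved by over 1.5 times, and the probes higher or lower in the mutant at all 3 times numbered 154 to 255 and 279 to 376. Normexp adds 50 to signals whose array medians lie between 26.1 and 97.2, which by construction shrinks differences of dim probes. It also changes the signal column and the background correction, and these were not tested apart. Testing only probes well above background on all 18 arrays called 2598 of 5501 at 12 h, against 3335 of 7650. With normexp, the mutant differed from the wild type in 558 probes at 12 h, 1052 at 16 h and 510 at 24 h, the wild type changed in 1384 from 12 to 24 h, 821 from 12 to 16 h and 1171 from 16 to 24 h, and the mutant in 1354, 504 and 909. The changes differed between strains in 296, 523 and 532 probes for the same intervals. Runs of neighbours under normexp numbered 10, 18 and 12 between strains at 12, 16 and 24 h, 24 in the wild type and 22 in the mutant from 12 to 24 h, and 5 for the difference between these. Runs of at least 4, a looser definition, numbered 180, 169, 137, 257, 370 and 118 in the same order. Spike-in scaling gave 259 runs in the wild type, and testing only probes well above background on all 18 arrays gave 43 runs for the difference between the strains' changes, with fewer probes tested. Fitting only the 6 arrays of 24 h gave 2024 calls and 46 runs, and fitting only those of 12 h gave 3817 calls and 145 runs. The cause of the spike-in and 24 h changes was not tested.

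Whether the replicate letters pair the arrays stays open. Of 7 pairs of arrays of 1 time and letter, 3 deviated together with a correlation over 0.1. The range was -0.08 to 0.31, and the other pairs had a median of -0.05. At 16 h the same-letter pairs lay at 0.26 and 0.31, but pairs of different letters reached 0.32 and 0.38. Across times, a check chosen after the data were seen, 2 of 7 same-letter pairs of the mutant (-0.12 to 0.16) and 2 of 7 of the wild type (-0.12 to 0.21) correlated over 0.1. Some of the groups compared share only part of their letters. With the letter as a block and only the arrays compared, which leaves fewer degrees of freedom, there were 1858 calls and 42 runs between strains at 16 h, 1680 calls and 37 runs at 24 h, 88 runs in the wild type from 12 to 24 h, 716 calls in the mutant from 12 to 16 h and 1742 from 16 to 24 h. The other counts stayed within 1.5 times. The highest-signal probe of a gene was not run as an alternative, because each ORF has 1 probe. Normexp on mean signals was not run, because only median signals were used here. Gene lists and scgA had no values to vary, and the series matrix was not used for comparisons of 16 h with other times.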

Other observations

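The stretches and probes named in this part, and all its tests, were chosen after their values were seen. In the wild type, all 22 probes from L10.orf1801 to L10.orf1822 rose from 12 to 24 h, with a median of 5.23, while in the mutant 10 rose and 12 were not called, with a median of 0.81. With groups not well above background at their bound, these medians were 5.13 and 0.92. The change differed between the strains for 19 of the 22, all lower in the mutant. At 24 h, 19 probes were lower in the mutant, with a median of -5.56, or -4.98 with groups not well above background at their bound and -3.11 with normexp background correction, and the mean level of the stretch was -2.63 ± 0.12 in the mutant and 2.10 ± 0.79 in the wild type (SD, n = 3). In the stretch from L10.orf6026 to L10.orf6071, 41 of 46 probes were higher in the mutant at 12 h, 9 were higher and 2 lower at 16 h, and 34 were higher and 5 lower at 24 h. The 24 h median was 3.64, and 1.62 with normexp background correction, 4.54 without wild-type replicate A and 3.11 without wild-type replicate C. Its mean level in the wild type was -2.51 ± 0.14 at 12 h, -0.09 ± 0.52 at 16 h and -2.08 ± 1.36 at 24 h, and in the mutant -0.53 ± 0.51, -0.11 ± 0.43 and 0.82 ± 0.12 (SD, n = 3). The probes well above background on all 9 wild-type arrays and on no mutant array were L10.orf0467, L10.orf2810, L10.orf4032 and L10.orf4356. At 16 h, L10.orf2810 was at least 37-fold lower in the mutant (adjusted p = 6.52e-09).

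The 5 probes well above background on all 9 mutant arrays and on no wild-type array were CUST_129_PI427711755, L10.orf0136, L10.orf0156, L10.orf0175 and L10.orf0184, all within 56 consecutive probe numbers. Their level at 16 h entered this choice, so the slide was tested on the 7 probes picked by the same rule on the 12 arrays of 12 and 24 h alone. All 7, of which 6 lay in this stretch, were called higher at 16 h, where both strains shared a slide, which argues against the slide as the cause. Not all of the 47 tested probes of this stretch differed: 24 were called higher in the mutant at 12 h, 25 at 16 h and 35 at 24 h, and 0 lower. These shares were 51.06%, 53.19% and 74.47%, against 20.68%, 19.06% and 20.71% of all tested probes. A strain difference at this place, from the deletion or from another change between the strains such as more copies, may account for the pattern, and neither this nor a chance placement of neighbours that change together was tested.

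The mutant arrays of 16 h lay nearer to the wild type at 12 h than at 16 h, with a root-mean-square log2 distance of 0.92 ± 0.09 to the former and 1.199 ± 0.041 to the latter (SD, n = 3). The ratio of the distances stayed at most 0.826 over 3 other scalings, which argues against the scaling. The 16 h arrays of both strains shared a slide and a scan day, and the wild-type 12 h arrays had others. A slide or scan-day effect would add distance to the wild type of 12 h and none to that of 16 h. The pattern is the opposite, which argues against slide and scan day as its cause. Of 37 probes that told the strains apart on the other 12 arrays, 9 followed the labels on all arrays of mutant 16 h and wild type 12 h and 0 followed swapped labels, which argues against a swap between these groups. Such probes cannot show an exchange of times within a strain, which was not tested. A later course of the wild-type changes in the mutant may account for the pattern. With a long delay, mutant 24 h arrays would lie nearer to the wild type of 16 h than of 24 h. With a shorter delay they could lie between these, so the distances cannot decide. The mean ratio of the distances to 16 h over 24 h was 0.969, but 1 of the 3 arrays lay at 1.03. With spike-in scaling all 3 lay between 1.26 and 1.42, and the explanation stays open. On the line from wild type 12 h (0) to wild type 24 h (1), the mutant stood at 0.04 ± 0.04 at 12 h, 0.02 ± 0.05 at 16 h and 0.63 ± 0.03 at 24 h (0.08, 0.07 and 0.80 with spike-in scaling), and the wild type at 0.33 ± 0.04 at 16 h, and the mutant's 12 h arrays lay at a distance of 1.236 ± 0.055 from the wild type of 12 h, farther than its 16 h arrays (SD, n = 3).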
